A study of Mus musculus with 6 samples.

How the data were processed

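RNA was measured in 6 libraries, 1 per treatment, each from pooled B16F10 tumours. Tumours of a treatment were pooled before RNA extraction, per the submitters' design text, and libraries were made with the QuantSeq 3′ FWD kit, which reads the 3′ ends of polyadenylated transcripts from an oligo-dT primer, and sequenced on a MiSeq for 151 cycles, per the labels' protocols. The deposited file is a single table of whole-number read counts per Ensembl mouse gene. The tools bcl2fastq, HISAT2 2.1.0 and HTSeq and the genome build GRCm38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting, trimming and the treatment of reads with several matches are not given in the sources used here. The number of mice per pool was not used here.

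The table had 43721 rows, of which 92 were spike-in names, all at 0, and 43629 were genes. Gene symbols, types, exon lengths and GRCm38 coordinates (counted from 1) came from GENCODE M21, which held 42462 of the genes. In all, 19725 genes had a count in at least 1 pool and 2592 in every pool. Genes with processed pseudogenes, near-identical paralogs or a nuclear copy of mitochondrial sequence (ribosomal protein genes, Eef1a1, Ftl1, Gapdh, globin genes, Hspa1b, MHC class I genes, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3) were kept, and their single values are uncertain, since the counting may have split or dropped their reads. The same holds for overlapping and antisense genes.

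Totals ran from 25521 to 1591673 counts, so 3 counts, taken as the limit that a count of 0 allows, were 1.89 CPM (counts scaled to 1e6 per pool) in the deepest pool, 112.6 CPM in the AZD5363+MK1775 pool, 8.86 CPM in the AZD5363+MK1775+anti-PD-1 pool and 67.0 CPM in the KS100 pool. Reads carry no molecular identifiers in the counts, so all intervals and limits cover counting error only. Thinned to 25521 counts, the pools detected a mean of 6054 genes (control), 6231 (anti-PD-1), 5638 (AZD5363+MK1775), 5722 (AZD5363+MK1775+anti-PD-1), 7729 (KS100) and 9373 (KS100+anti-PD-1). Background was gauged from 8742 protein-coding genes at 0 in the control and anti-PD-1 pools, with 26.97 Mb of exon. Their counts per Mb of exon, carried over to all exons, would make up 3.06%, 1.54%, 19.1% and 39.0% of counts in the 4 inhibitor pools in the order above, and the expected background of a gene list is that rate times its exon length. A later test argued against an even spread of these counts in the KS100 pools, so the expected counts are a rough guide there. Pools were also correlated on log2 of CPM plus 20 across nuclear protein-coding genes, with CPM scaled to these genes and genes at 0 included. The Pearson r was 0.977 between the control and anti-PD-1 pools and 0.434 between the control and KS100+anti-PD-1 pools. Genes are not independent replicates.

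Which tests, samples, alternatives, gene lists and naming rule were used was fixed before the data were examined, except where stated. The 4 arm effects (anti-PD-1, AZD5363+MK1775, KS100, and AZD5363+MK1775 against KS100) were fitted with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr at its defaults, which kept 4912 genes, and the quasi-likelihood test, as an additive model of inhibitor arm and antibody over all 6 pools. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The SE given with a log2 change is that change divided by the square root of the test's F statistic. It was not fitted as a standard error, and it is only a rough guide for genes near 0 counts. The model leaves 2 residual degrees of freedom, and any interaction of inhibitor and antibody is part of its residual, so pools of another treatment serve as replicates. The common dispersion was 0.215 and the TMM factors ran from 0.675 in the AZD5363+MK1775+anti-PD-1 pool to 1.156 in the AZD5363+MK1775 pool. The difference between the antibody's effects in 2 inhibitor arms was not tested. The filter's cutoff is in CPM, so a gene met it on fewer counts in a shallow pool than in a deep one. Genes low in control could thus enter through the shallow inhibitor pools where they were high, while falls there were hard to call.

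The 9 comparisons of 2 pools have no replicates and no p-values. A gene with at least 20 counts in 1 of the 2 pools was called higher or lower where its TMM-normalised ratio was at least 2 in either direction and the 95% exact conditional (Clopper-Pearson) interval of the ratio lay wholly beyond 1.5-fold. A ratio against 0 counts is given as a lower bound against 3 counts in that pool. The median log2 ratio of all genes tested in a pair covers genes with at least 20 counts in 1 of the 2 pools. That of an arm effect covers the 4912 genes fitted. Both depend on this minimum, so values without it are given too. The 38 gene lists, of cell types, pathways and drug targets, were written from general knowledge. For each list and comparison the median log2 ratio of the members kept, with a prior count of 2, was ranked among 10000 random lists matched on mean expression in 20 bins. Of 351 such medians 108 lay outside the central 95%, 64 high and 44 low. The sums of counts over each list, with their exact intervals, were added after the data were seen, and the lists described were chosen from all 38 after their values were seen. A second skeletal muscle list of 19 genes was also written after the data were seen.

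Genes were named by rule. For an arm effect these were the 10 called genes with the largest and the 10 with the smallest log2 fold change that went the same way in every pool pair, or all where fewer were called. Where fewer than 5 were called in a direction, the uncalled genes that went the same way by most were added. For a pool pair they were the 10 highest and the 10 lowest by the interval's bound, and for a list up to 4 members, 2 by expression and 2 by change. Drug targets were named, and predicted gene models were counted but not named. Cdt1, Hspe1, Rab38, Slc7a11, Acta1 and Irf1 in the arm effects, mt-Co1 and list members beyond 4 of a list were chosen after their values were seen. A few genes that the rule names are not reported.

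The fits were tested on simulated data with 200 changed genes among 4912. Changes of 4-fold were called for 2.5% of them in the anti-PD-1 effect, 4% in the AZD5363+MK1775 effect and 1% in the KS100 effect, and 16-fold changes for 80.5%, 73% and 52.5%, so the arm effects miss most changes of moderate size. The pair rule was tested with 200 changes of 4-fold among 43629 genes, placed in genes with at least 20 counts over the 2 pools together. It recovered 87.0% for the anti-PD-1 pool, 26.5% for AZD5363+MK1775, 34.5% for KS100, 66.5% for AZD5363+MK1775+anti-PD-1 and 27.0% for KS100+anti-PD-1, each against control. For the antibody within an inhibitor arm it recovered 38.5% in the AZD5363+MK1775 arm and 58.5% in the KS100 arm, and for the combinations against anti-PD-1 alone 68.5% and 23.5% in the same order. With counting error alone simulated, false calls numbered 13 for AZD5363+MK1775, 16 for KS100 and 20 for KS100+anti-PD-1 over control. They ran from 0 for KS100+anti-PD-1 over KS100 to 24 for KS100+anti-PD-1 over anti-PD-1, where 47 changes were recovered.

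Alternatives were DESeq2 (1.42.0) size factors, library totals, other count minimums and fold bounds, the DESeq2 Wald test, limma-voom (limma 3.58.1), a fit without the other factor, and leaving out each pool. Library totals here are each pool's counts over the 4912 genes fitted, without a normalisation factor. They were 35194 in the KS100 pool and 15385 in the KS100+anti-PD-1 pool, against 44748 and 25521 over all genes. Further ones were chosen after seeing the data: nuclear protein-coding genes alone, genes over 0 in the control and anti-PD-1 pools alone, all pools thinned to the shallowest, and fits without both pools of an inhibitor arm. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.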

Results

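Gene counts were measured in B16F10 mouse melanoma tumours grown in 8-week-old female C57BL/6J mice and collected when the control tumours reached 2000 mm3. The 6 libraries were each made from pooled tumours of 1 treatment. They cross 3 inhibitor arms with 2 antibodies. The arms were DMSO with no inhibitor, AZD5363 with MK1775, which inhibit the kinases AKT and WEE1, and KS100, an inhibitor of aldehyde dehydrogenases. The antibodies were control IgG and anti-PD-1, which blocks an inhibitory receptor of T cells. The treatment labels name DMSO only in the arm with no inhibitor. The comparisons address what the antibody, the inhibitors and their combinations did to the tumour transcriptome. There was 1 library per treatment, so no single comparison of 2 pools had a replicate check. In those comparisons a gene is called higher or lower by a rule of size, and the 95% intervals given after ratios cover counting error only.

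The libraries held 1591673 counts in the control pool, 1002088 in the anti-PD-1 pool, 26639 in the AZD5363+MK1775 pool, 338474 in the AZD5363+MK1775+anti-PD-1 pool, 44748 in the KS100 pool and 25521 in the KS100+anti-PD-1 pool, a 62.4-fold range. A gene at 0 could hold up to 3 counts, which is 1.89 CPM in the control pool and 118 CPM in the KS100+anti-PD-1 pool. Mitochondrial genes took 1.89% of counts in the control pool, 1.29% in the anti-PD-1 pool, and 13.2%, 19.8%, 17.1% and 14.6% in the 4 inhibitor pools in the order above. The ribosomal RNA genes mt-Rnr1, mt-Rnr2 and Gm42418 took 0.121% of control counts and 27.4% (27.3 to 27.6, exact binomial interval) of those of the AZD5363+MK1775+anti-PD-1 pool. A set of 8742 protein-coding genes had 0 counts in both the control and the anti-PD-1 pool. These genes took 0.717% and 0.36% of counts in the pools with AZD5363+MK1775, without and with antibody, against 4.47% and 9.15% in the KS100 pools.

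**Figure D1:**
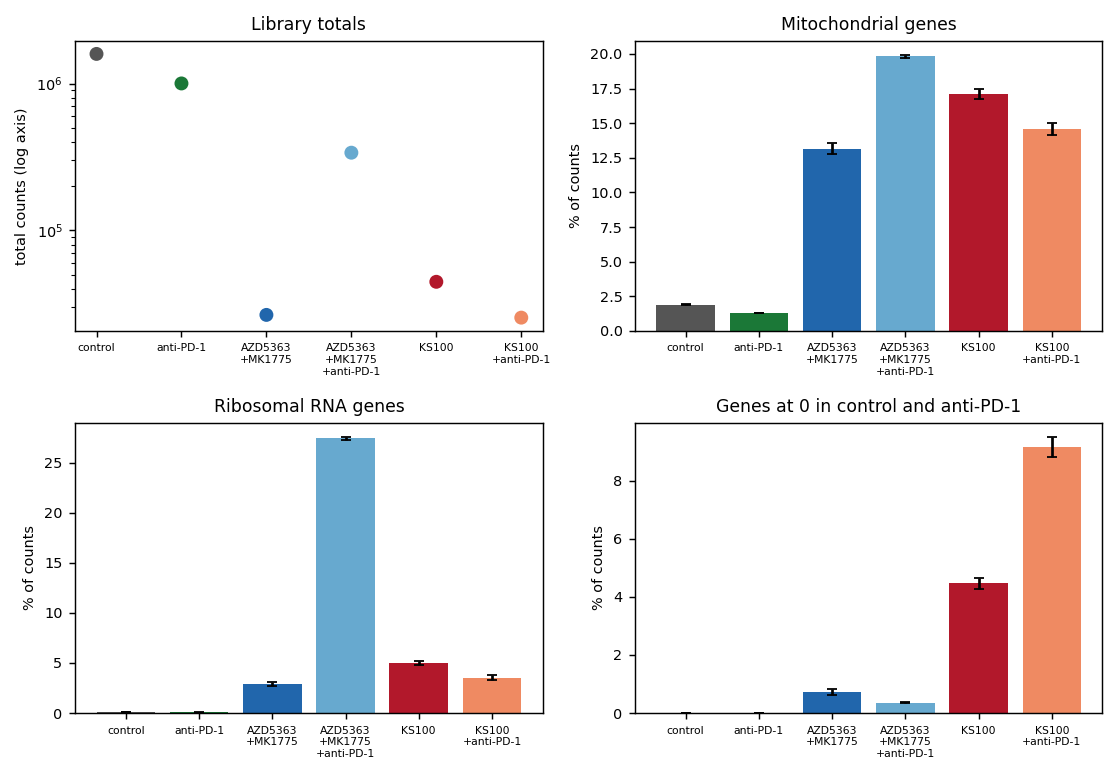
Library totals (log axis) and the share of counts (percent, with 95% exact binomial intervals) taken by mitochondrial genes, by ribosomal RNA genes and by protein-coding genes at 0 in the control and anti-PD-1 pools, for the 6 pools. The 4 inhibitor pools held between 25521 and 338474 counts and larger mitochondrial shares than the other pools.

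The transcripts of the proteins the treatments target were measured only in part. Akt1 had 909 counts in the control pool, 398 in the anti-PD-1 pool, and 8, 112, 9 and 0 in the inhibitor pools. Its ratio to control was 0.489 (0.211 to 0.968) in the AZD5363+MK1775 pool and 0.936 (0.762 to 1.14) in the AZD5363+MK1775+anti-PD-1 pool. Akt2 had 27 counts in the control pool, 22 in the anti-PD-1 pool and 7 in the AZD5363+MK1775+anti-PD-1 pool, and Pkmyt1 had 78, 43 and 4. Wee1 had 1 count in the control pool and 1 in the AZD5363+MK1775+anti-PD-1 pool. Cdk1, the kinase that WEE1 restrains, was not past the rule in the AZD5363+MK1775 pool at 0.609 (0.314 to 1.07) and was lower in the AZD5363+MK1775+anti-PD-1 pool at 0.208 (0.14 to 0.299). Pdcd1, which encodes PD-1, had 1 count in all, in the AZD5363+MK1775+anti-PD-1 pool. Its ligand gene Cd274 had 6 counts in the control pool, 0 in the anti-PD-1 pool and 19 in the AZD5363+MK1775+anti-PD-1 pool, and Pdcd1lg2 was listed at 0 everywhere. Aldh2 had 309 and 252 counts in the control and anti-PD-1 pools and 2, 1, 2 and 1 in the inhibitor pools. It was lower than control in the AZD5363+MK1775+anti-PD-1 pool at 0.0246 (0.00062 to 0.138), while its KS100 ratio of 0.299 (0.036 to 1.09) was not past the rule. Trp53 was higher in the AZD5363+MK1775+anti-PD-1 pool at 14.2-fold (8.50 to 24.4), on 45 counts against 24. Aldh1a1 and Aldh1a3 had at most 7 counts in any pool and Aldh3a1 none.

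Anti-PD-1 alone was set against control IgG to ask what the antibody did to tumours without an inhibitor. The anti-PD-1 pool held more stroma, muscle and blood transcripts. Of 14 fibroblast and matrix genes tested, 13 were higher and none lower, and their summed counts were 5.06-fold those of control (4.71 to 5.45). Col1a1 was 15.2-fold higher (12.4 to 18.7), Col1a2 14.2-fold (10.2 to 20.2) and the collagen cross-linking gene Lox 29.6-fold (12.3 to 93.4), and Mfap5, at 0 in control, was at least 15.4-fold higher. Sparc, at 1.77-fold, was the member not past the rule. All 8 skeletal muscle genes tested were higher, with a summed ratio of 12.1 (9.94 to 14.9), led by Myh4 at 74.9-fold (20.2 to 627), Tnnt3 at 49.4-fold (8.26 to 2012), Ttn at 14.9-fold (8.87 to 26.7) and Acta1 at 10.8-fold (8.02 to 14.7). The globin genes Hba-a1, Hbb-bt and Hbb-bs were 11.1-fold, 7.28-fold and 5.88-fold higher, each uncertain as a single gene because globin copies are nearly identical. Of 5 erythroid genes tested, 4 were higher and 1 lower. The fat cell and muscle gene Car3 was 25.5-fold higher and Fabp4 2.38-fold, and of 10 endothelial genes 3 were higher, among them Plvap at 3.25-fold and Esam at 2.67-fold.

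Macrophage and chemokine genes were higher in the anti-PD-1 pool, while T cell and interferon-response genes were not. Of 7 macrophage genes tested 4 were higher and none lower, with a summed ratio of 1.93 (1.76 to 2.12). They included Arg1 at 35.5-fold (5.77 to 1463), Pf4 at 3.80-fold (2.38 to 6.25) and the complement gene C1qa at 3.63-fold (2.62 to 5.09). Apoe, at 1.5-fold, was not past the rule. Of 9 chemokine and cytokine genes 4 were higher, with Ccl8 at 7.98-fold (3.28 to 23.4), Ccl9 at 6.18-fold (2.25 to 21.1) and Cxcl10 at 2.05-fold (1.61 to 2.62). The T cell list held 10 counts against 14 in control, a ratio of 1.10 (0.438 to 2.67), so no difference was detectable at this depth. Cytotoxic effector genes had a ratio of 1.54 (0.851 to 2.80). Interferon-gamma response genes were at 1.04 (0.924 to 1.17), with 1 of 9 higher. Cxcl10 held 32.8% of these counts, and the list's median log2 ratio was -0.39, at percentile 1.7 of matched random lists. Of 14 MHC class I pathway genes 2 were lower, Tap2 at 0.14 (0.016 to 0.571) and Psmb9 at 0.229 (0.0582 to 0.657), and the summed ratio was 0.93 (0.878 to 0.986), and 0.968 (0.913 to 1.03) with library totals. MHC class II genes were at 1.19 (0.985 to 1.44), with none of 5 past the rule.

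Sterol synthesis and heat shock genes were lower in the anti-PD-1 pool, and unfolded protein and integrated stress response genes higher. Of 16 cholesterol synthesis genes 8 were lower and none higher, with a summed ratio of 0.515 (0.487 to 0.544). Insig1 was at 0.293 (0.166 to 0.488), Fdft1 at 0.400 (0.235 to 0.654) and Msmo1 at 0.499 (0.43 to 0.579). Of 10 heat shock genes 4 were lower, with a summed ratio of 0.621 (0.602 to 0.64). They were Hspa1b, which has a near-identical copy, at 0.0909 (0.0501 to 0.153), Dnajb1 at 0.27 (0.199 to 0.36), Hspe1 at 0.381 (0.345 to 0.421) and Hsp90aa1 at 0.456 (0.41 to 0.505). The cholesterol and heat shock lists had medians below every one of 10000 random lists matched on expression. Of 15 stress response genes 5 were higher, with a summed ratio of 1.19 (1.16 to 1.24) and a median at percentile 99.8 of matched lists, among them Trib3 at 4.84-fold (3.59 to 6.61) and Chac1 at 2.87-fold (1.65 to 5.13), while the chaperone gene Hsp90b1 stood at 0.619. The cystine transporter gene Slc7a11 was 9.37-fold higher (6.34 to 14.3) and Hmox1 3.10-fold (2.56 to 3.77). Of 17 p53 target genes 4 were higher, with Gdf15 at 4.32-fold (2.35 to 8.40) and Rrm2b at 2.99-fold (1.55 to 5.99), and a summed ratio of 1.48 (1.38 to 1.58). FOXO target genes, which active AKT represses, summed to 1.40 (1.28 to 1.54), with 1 of 13, Fbxo32, past the rule at 3.5-fold. Melanocyte and pigment genes were lower as a sum at 0.789 (0.776 to 0.802), with Kit higher at 4.54-fold, 2 of 19 lower and Dct not past the rule at 0.856. Mitochondrially encoded genes summed to 0.679 (0.665 to 0.693), with none of 6 past the rule.

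By the size rule 218 genes were higher and 174 lower in the anti-PD-1 pool than in the control pool, 392 in all. Other genes lower were Kpna2 at 0.0672 (0.0079 to 0.257), Kcnj13 at 0.0759 (0.0152 to 0.233) and Slc25a14 at 0.0883 (0.0103 to 0.344). Rpl35, Eef1a1, Ftl1, Pgk1 and Eno1 were also lower, but these genes have processed pseudogenes that can take or split their reads, so their values are uncertain. With all pools thinned to the depth of the shallowest, 10 genes passed the rule in this pair.

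AZD5363+MK1775 was set against control to ask what the kinase inhibitors did without the antibody. The AZD5363+MK1775 pool held more mitochondrial and fewer pigment transcripts. All 10 mitochondrially encoded genes tested were higher, with a summed ratio of 5.73 (5.51 to 5.95). The values were 4.89-fold for mt-Cytb (4.62 to 5.18) and 6.27-fold for mt-Nd4 (5.69 to 6.90). The mt-Co2 value of 355-fold and the mt-Atp6 value of 653-fold are uncertain, because a nuclear copy of that stretch of the mitochondrial genome can take their reads. Of 17 pigment genes 6 were lower and none higher, with a summed ratio of 0.439 (0.392 to 0.49), among them Rab38 at 0.149 (0.018 to 0.54), Pmel at 0.258 (0.15 to 0.414), Tyrp1 at 0.426 (0.278 to 0.625) and Dct at 0.466 (0.399 to 0.541). Of 23 mitosis genes 2 were lower, Plk1 at 0.237 (0.102 to 0.467) and Birc5 at 0.383 (0.204 to 0.657), with a summed ratio of 0.53 (0.425 to 0.653) and Top2a not past the rule at 0.575. Of 23 DNA replication genes 2 were lower, and they summed to 0.467 (0.351 to 0.608). The medians of the mitosis and replication lists lay at percentiles 18.3 and 3.1 of matched random lists, inside the central 95%. Rrm2, which makes deoxynucleotides, was at 0.19 (0.0518 to 0.488), and Cdt1 at 0.216 (0.0261 to 0.786) was not past the rule.

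FOXO target genes, at 1.02 (0.59 to 1.64), and p53 target genes, at 0.878 (0.581 to 1.27), had no member past the rule in the AZD5363+MK1775 pool. MHC class I genes summed to 0.433 (0.277 to 0.645), with B2m at 0.338 (0.146 to 0.668) and none of 14 past the rule. The interferon-gamma list held 5 counts, a ratio of 0.389 (0.126 to 0.912), and the skeletal muscle list 0 counts, which allows up to 1.86-fold. Ribosomal protein genes were at 1.03 (0.961 to 1.11), with 1 of 24 higher and 2 lower. Other genes higher were Ppip5k1 at 23.2-fold (11.8 to 43.4), Ctdsp1 at 21.2-fold (8.11 to 49.8) and Arhgef10l at 10.9-fold (5.93 to 18.7). Tuba1a had 0 counts, at least 5.36-fold lower, as had Rbbp7 at 4.61-fold and the RNA methyltransferase gene Nsun2 at 4.2-fold, both also lower bounds. Mdh1 was at 0.045 (0.00114 to 0.251), Psap at 0.104 (0.0214 to 0.304), Cyb5a at 0.132 (0.0567 to 0.259) and Cct7 at 0.149 (0.0546 to 0.325). The rule called 131 genes higher and 102 lower, 233 in all. The split was 175 and 65 with DESeq2 size factors, and 159 and 78 with library totals. The median log2 ratio of all genes tested was -1.03, and -0.89 with DESeq2 size factors. Genes without counts in this shallow pool count as lower there, and with no minimum count the median was -0.82.

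KS100 was set against control to ask what the aldehyde dehydrogenase inhibitor did without the antibody. Pigment, antigen-presentation and DNA replication transcripts were lower in the KS100 pool, and mitochondrial transcripts and many genes with no counts in control were higher. The fibroblast and matrix list, with 8 members kept, had a median log2 ratio of 1.44, at percentile 99.5 of matched random lists. Of 17 pigment genes 7 were lower and none higher, with a summed ratio of 0.299 (0.263 to 0.337). Slc24a5 was at 0.0778 (0.0212 to 0.199), Pmel at 0.126 (0.0604 to 0.232), Slc45a2 at 0.155 (0.0567 to 0.338), Dct at 0.298 (0.249 to 0.353) and Tyrp1 at 0.354 (0.231 to 0.519). MHC class I genes summed to 0.255 (0.148 to 0.408), with B2m at 0.316 (0.144 to 0.601) and Calr at 0.0735 (0.00186 to 0.411) lower among 14. Of 23 mitosis genes 4 were lower, among them Ccna2 at 0.107 (0.0027 to 0.6), Cdk1 at 0.126 (0.026 to 0.37) and Top2a at 0.254 (0.11 to 0.503), and the list summed to 0.479 (0.388 to 0.585), with its median at percentile 10.1 of matched random lists, inside the central 95%. DNA replication genes summed to 0.458 (0.353 to 0.584), with 2 of 23 lower.

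Unfolded protein response genes were lower in the KS100 pool, and NRF2, glycolysis and hypoxia genes were lower as sums, with medians at percentiles 13, 16.4 and 16.4 of matched random lists, inside the central 95%. Unfolded protein response genes summed to 0.487 (0.388 to 0.603), with a median at percentile 1.2 and 2 of 15 lower, Hspa5 at 0.378 (0.242 to 0.564) and Hsp90b1 at 0.182 (0.073 to 0.376). NRF2 target genes also summed to 0.487 (0.388 to 0.604), with 2 of 13 lower, among them Prdx1 at 0.283 (0.184 to 0.415). Glycolysis genes were at 0.588 (0.507 to 0.678), with none of 13 past the rule, and hypoxia genes at 0.604 (0.526 to 0.691), with 1 of 19 lower. That gene, Kdm3a, had 0 counts and was at least 3.54-fold lower, and Ldha stood at 0.624. Heat shock genes were at 1.08 (0.968 to 1.21) and at 0.942 with library totals, with 1 of 10 higher and 3 lower, while their median log2 ratio was -1.88, at percentile 0.1 of matched random lists. Aldehyde dehydrogenase genes summed to 0.632 (0.314 to 1.14), and to 0.55 (0.273 to 0.989) with library totals, with none of 9 past the rule. All 8 mitochondrially encoded genes tested were higher, with a summed ratio of 9.25 (8.99 to 9.52).

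Among the other genes higher in the KS100 pool, Has2os, Nxph1 and Creb5 had 0 counts in control and were at least 415-fold, 385-fold and 308-fold higher. Csmd3 was 923-fold higher (148 to 38250) on 20 counts against 1, Greb1 299.9-fold (104 to 1183), and the zinc transporter gene Slc30a4 42.0-fold (29.2 to 60.3). Lower genes included Gtf2i at 0.0753 (0.00911 to 0.273), Psap at 0.144 (0.0466 to 0.336), Ubb at 0.202 (0.115 to 0.328) and Mif at 0.206 (0.134 to 0.302). Tspan10 had 0 counts and was at least 4.15-fold lower. The rule called 358 genes higher and 148 lower, 506 in all, and 304 and 230 with library totals. The median log2 ratio of all genes tested was -0.49, -0.69 with library totals and -0.33 with no minimum count.

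AZD5363+MK1775 with anti-PD-1 was set against control, and against each part alone, to ask what the combination did. Its pool stood apart by interferon-response and antigen-presentation genes. All 16 interferon-gamma response genes tested were higher than in control, with a summed ratio of 17.6 (16.1 to 19.3). The GTPase genes Iigp1 and Igtp were 63.3-fold (44.7 to 92.1) and 25.3-fold (19.0 to 34.1) higher, Irf1 10.1-fold (8.12 to 12.7), and Ciita, at 0 in control, at least 63.3-fold. All 15 MHC class I pathway genes tested were higher, with a summed ratio of 5.84 (5.54 to 6.17): H2-K1 15.2-fold (13.3 to 17.4), H2-D1 10.2-fold (8.49 to 12.2), B2m 3.43-fold (3.10 to 3.78) and the immunoproteasome gene Psmb8 91.2-fold (39.9 to 257). All 7 MHC class II genes tested were higher, with a summed ratio of 14.9 (12.8 to 17.4), among them H2-Eb1 at 37.1-fold, H2-Aa at 28.9-fold, Ctss at 10.7-fold and Cd74 at 6.24-fold. All 8 type I interferon response genes tested were higher, with a summed ratio of 9.26 (8.31 to 10.3). Ifi44 was 289-fold higher (48.8 to 11700) on 38 counts against 1, Rsad2 18.2-fold, Bst2 3.09-fold, and Xaf1, at 0 in control, at least 78.5-fold.

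**Figure D2:**
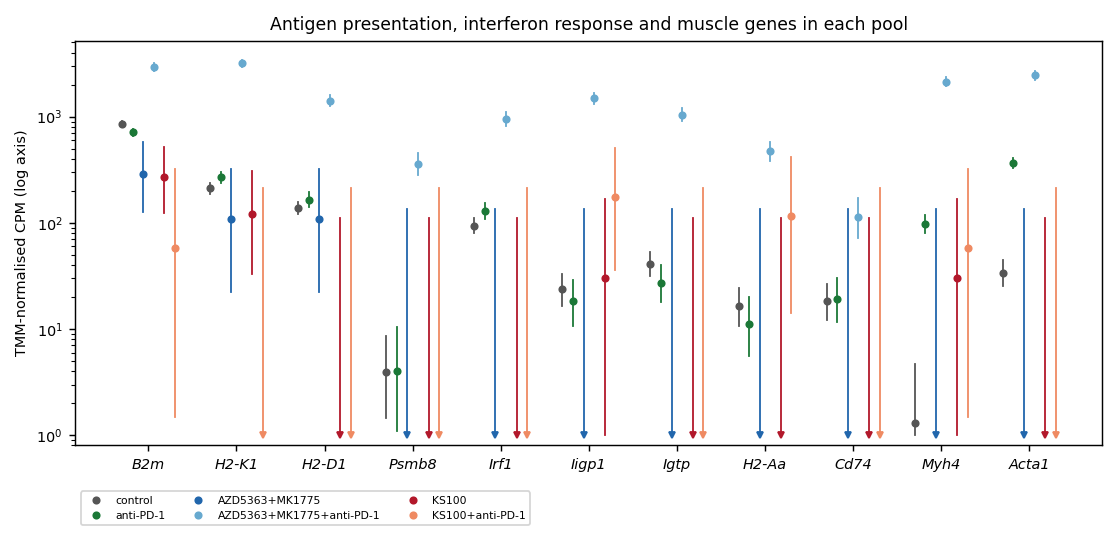
TMM-normalised CPM (log axis) of antigen-presentation, interferon-response and muscle genes in the 6 pools, with 95% exact Poisson intervals; downward triangles mark 0 counts. H2-K1, Irf1, Iigp1 and Acta1 stand above the other pools in the AZD5363+MK1775+anti-PD-1 pool, and upper limits in the shallow pools are wide.

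Lymphocyte transcripts were few but more frequent in the AZD5363+MK1775+anti-PD-1 pool. The T cell list held 47 counts against 14 in the deeper control pool, a ratio of 25.5 (13.8 to 50.2), where 3.2 counts would come from background spread evenly over exons. Cytotoxic effector genes were at 8.81 (4.98 to 15.7), with Ccl5 at 4.18-fold (1.81 to 9.15). Checkpoint and exhaustion genes were at 3.94 (2.64 to 5.82). Regulatory T cell genes were at 7.84 (4.63 to 13.3), but this sum rested mostly on Ikzf2, with 27 counts at 9.32-fold (5.11 to 17.2). It therefore says little about the list as a whole. Of 6 chemokine genes 5 were higher, with a summed ratio of 6.13 (5.19 to 7.25), Cxcl9 at 20.5-fold (12.1 to 36.2) and Cxcl10 at 6.45-fold (4.90 to 8.48). Of 5 macrophage genes 2 were higher, with C1qa at 11.5-fold (8.08 to 16.6), Apoe at 0.918 and a summed ratio of 2.34 (2.03 to 2.69).

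Muscle transcripts were higher still than in the anti-PD-1 pool. All 15 skeletal muscle genes tested were higher than in control, with a summed ratio of 234 (194 to 285), led by Myh4 at 1633-fold (449 to 13530), Ckm at 1212-fold (333 to 10050), Ttn at 455-fold (279 to 799) and Acta1 at 71.9-fold (53.9 to 97.6). Car3 was 581-fold higher, and with it 1 of 3 fat cell genes tested was past the rule, at a summed ratio of 3.86 (3.22 to 4.61). Fibroblast and matrix genes summed to 4.38 (3.94 to 4.87), with 3 of 7 higher, Col1a2 at 15-fold and Sparc at 7.64-fold, and Col1a1 not past the rule at 2.01-fold. Erythroid genes were lower at 0.214 (0.16 to 0.281), with 3 of 5 lower and Hbb-bs at 0.0315 (0.00648 to 0.0924).

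Hypoxia genes were lower in the AZD5363+MK1775+anti-PD-1 pool, with 8 of 19 lower, 1 higher and a summed ratio of 0.351 (0.326 to 0.377). Ldha was at 0.232 (0.206 to 0.26), Bnip3 at 0.12 (0.0751 to 0.183), Adm at 0.117 (0.014 to 0.431) and Hilpda, outside the list, at 0.0563 (0.0206 to 0.123), while Hk2 was 4.22-fold higher (3.52 to 5.04). Of 24 ribosomal protein genes 12 were lower, with a summed ratio of 0.635 (0.614 to 0.657), Rpl37 at 0.237 and Rpl11 at 0.211. Rplp1 stood at 1.17, and fell below 1 with library totals. Pigment genes summed to 0.795 (0.77 to 0.821), with 3 of 17 higher, among them Tyr at 4.01-fold and Rab27a at 3.57-fold, 3 lower, and Dct at 0.889. Of 6 mitochondrially encoded genes 5 were higher, with a summed ratio of 4.74 (4.65 to 4.83), mt-Nd2 at 42.2-fold and mt-Nd5 at 20.4-fold. The nuclear RNA Malat1 had 1841 counts against 188 in control. Other genes lower were Atp5mpl at 0.074 (0.0505 to 0.105), Polr2k, at least 10.8-fold, and Adam12, at least 9.26-fold.

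The rule called 1202 genes higher and 646 lower than control, 1848 in all. With library totals, which do not correct for the ribosomal RNA in this pool, 616 were higher and 1694 lower. The median log2 ratio of all genes tested moved from -0.01 to -0.65, and was 0.26 with TMM and no minimum count. Short and long genes differed: in 5 bins of exon length, the median log2 ratio was -0.55, -0.35, -0.02, 0.33 and 0.93, from a median of 1821 bp to 11726 bp. Only the interferon-gamma and MHC class I genes were tested against genes matched on length. The values of the other lists in this pool, ribosomal protein genes among them, are not separated from this trend.

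Against the AZD5363+MK1775 pool, which had the same inhibitors without antibody, the interferon-gamma list was 45.3-fold higher (19.4 to 140), with 13 of 16 genes past the rule, among them Iigp1 at least 13.7-fold. MHC class I genes were 13.5-fold higher (9.05 to 21.1), with 9 of 13 past the rule, H2-K1 at 29.3-fold (9.98 to 142) and B2m at 10.1-fold (5.11 to 23.6). MHC class II genes had 506 counts against 0. Ttn was at least 43.6-fold higher, the lipase gene Mgll 51.0-fold (14.1 to 422) and Malat1 22.9-fold (12.8 to 45.9). Hypoxia genes were lower at 0.348 (0.304 to 0.399), with 3 of 7 lower and 1 higher. Ribosomal protein genes were lower at 0.616 (0.57 to 0.665), with 6 of 22 past the rule, and erythroid genes at 0.351 (0.209 to 0.612). Pigment genes summed to 1.81 (1.62 to 2.04), and to 1.06 (0.944 to 1.19) with library totals, with a median at percentile 96.1, inside the central 95%, 4 of 16 higher and Rab38 at 8.40-fold (2.28 to 70.2). The rule called 309 genes higher and 104 lower, 413 in all, and 80 and 232 with library totals. The median log2 ratio of all genes tested was 1.10, 0.96 with DESeq2 size factors, 0.43 with library totals and 0.65 with no minimum count.

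Against the anti-PD-1 pool, which had the antibody without inhibitors, all 16 interferon-gamma genes tested were higher, with a summed ratio of 16.9 (15.3 to 18.8), Gbp4 at 167-fold (44.6 to 1409) and Iigp1 at 82.0-fold (51.0 to 140). All 13 MHC class I genes were higher at 6.28 (5.91 to 6.68), all 7 MHC class II genes at 12.5 (10.6 to 14.8) and all 8 type I interferon genes at 10.9 (9.55 to 12.4). Of 16 muscle genes 15 were higher, with a summed ratio of 19.3 (17.9 to 20.8). Of 9 heat shock genes 4 were higher, with a summed ratio of 2.0 (1.91 to 2.1), a median at percentile 94.7 and Hsp90aa1 at 5.66-fold. Of 14 matrix genes 5 were lower and 1 higher, with Col1a1 at 0.132 (0.0874 to 0.192) and a summed ratio of 0.865 (0.789 to 0.947). Erythroid genes were at 0.0684 (0.0513 to 0.0894), with 3 lower, and hypoxia genes at 0.308 (0.285 to 0.331), with 10 of 19 lower and 3 higher. Of 16 p53 targets 4 were lower, with Ddit4 at 0.0612 (0.0125 to 0.181) and a summed ratio of 0.53 (0.452 to 0.617). Of 23 ribosomal protein genes 11 were lower and 1 higher, at 0.628, with a median at percentile 5.0. Hmox1 stood at 0.0307 (0.0037 to 0.112) and Nr4a1 at 0.0533 (0.0195 to 0.117). The rule called 1000 genes higher and 579 lower, 1579 in all, and 508 and 1766 with library totals. Library totals moved the median log2 ratio of all genes tested to -0.74, and no minimum count with TMM to 0.22.

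KS100 with anti-PD-1 was set against control and against each part alone to ask the same of the other combination. Pigment and antigen-presentation transcripts were lower in the KS100+anti-PD-1 pool than in control. The fibroblast and matrix list, with 8 of 21 members kept, had a median log2 ratio of 2.16, at percentile 99.9 of matched random lists. Its median was -1.27 against the anti-PD-1 pool, at percentile 30.6, and 0.1 against the KS100 pool, at percentile 80.1. Background in this pool was not separated from these values. Of 17 pigment genes 8 were lower and none higher, with a summed ratio of 0.174 (0.138 to 0.217), Mitf, which encodes the melanocyte regulator, at 0.0473 (0.0012 to 0.264), Pmel at 0.0725 (0.0149 to 0.212) and Dct at 0.2 (0.147 to 0.266). MHC class I genes had 2 counts, a ratio of 0.0574 (0.00695 to 0.208), with B2m at 0.0673 (0.0017 to 0.376). Of 24 ribosomal protein genes 12 were lower, with a summed ratio of 0.375 (0.324 to 0.433) and Rpl37 at 0.0276 (0.0007 to 0.154). Hypoxia genes summed to 0.334, with 4 of 19 lower. The medians of the ribosomal protein and hypoxia lists lay at percentiles 40.8 and 64.5 of matched random lists, no lower than other genes of their expression in this pool. The interferon-gamma list held 31 counts, where 8.4 would come from background spread evenly over exons, a ratio of 3.84 (2.59 to 5.50). Of its 9 genes tested 2 were higher. Counts of silent genes were uneven in the KS100 pools, so an excess over an even background may itself be background. All 6 mitochondrially encoded genes tested were higher, with a summed ratio of 9.24 (8.89 to 9.59) and mt-Nd2 at 102-fold (92 to 114).

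Other genes higher in the KS100+anti-PD-1 pool were Traf5 at 295-fold (114 to 898), the imprinted antisense RNA Kcnq1ot1 at 113-fold (85.6 to 150), Ankrd12 at 52.5-fold (26.4 to 101) and Uvssa at 40.7-fold (21.5 to 74.1). Kcnq1ot1 overlaps Kcnq1 on the other strand, and whether counting used strand is not given in the sources used here. Lower genes included Atp6v1f, Cox7a2 and Psap, at 0 counts and at least 9.67-fold, 7.58-fold and 6.05-fold lower, Ubb at 0.0242 (0.00061 to 0.135), Cox6c at 0.0678 (0.014 to 0.198) and Mif at 0.106 (0.0427 to 0.219). The rule called 365 genes higher and 227 lower, 592 in all, and 419 and 136 with DESeq2 size factors. The median log2 ratio of all genes tested was -2.48 and -2.20 in the same order, and -0.325 with TMM and no minimum count. T cell genes had 16 counts, where 6.2 would come from even background, against 2 counts in the KS100 pool, where 5.3 would. Natural killer cell genes had 3 and 4 counts in the 2 pools, near the 5.0 and 4.3 of an even background. Counts of silent genes were uneven in these pools, so these comparisons do not separate signal from background.

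Against the KS100 pool, ribosomal protein genes were lower at 0.307 (0.262 to 0.359), with 9 of 17 past the rule, Rpl37 at 0.0114 (0.00029 to 0.0641) and the elongation factor gene Eef2 at 0.0349 (0.00087 to 0.203). Pigment genes were at 0.584 (0.449 to 0.752), with 1 of 3 lower and a median at percentile 70.6, and cholesterol synthesis genes at 0.402 (0.227 to 0.673). Mitochondrially encoded genes summed to 0.998 (0.955 to 1.04), and to 1.19 with library totals over the fitted genes. Of 8 tested 2 were higher, mt-Nd2 at 3.62-fold and mt-Nd5 at 3.21-fold, and 4 lower, among them mt-Co1 at 0.381. Traf5 was 38.4-fold (6.14 to 1590) and Kcnq1ot1 5.85-fold (4.05 to 8.63) higher. The rule called 9 genes higher and 71 lower, 80 in all. The median log2 ratio of all genes tested was -1.35, -1.16 with DESeq2 size factors and -1.11 with library totals. With no minimum count that median was 0.2, so its direction rests on the minimum. Against the anti-PD-1 pool, Mitf was at 0.0451 (0.00114 to 0.252), Dct at 0.234 (0.172 to 0.311) and Hbb-bs at 0.0416 (0.005 to 0.15), and Traf5 382-fold (113 to 2008) and mt-Nd2 163-fold (142 to 189) higher. Erythroid genes summed to 0.103 (0.0415 to 0.213) in that pair. The rule called 232 genes higher and 213 lower, 445 in all, and 292 and 143 with DESeq2 size factors. The median log2 ratio of all genes tested was -2.09 and -1.86 in the same order, and -0.327 with TMM and no minimum count.

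**Figure D3:**
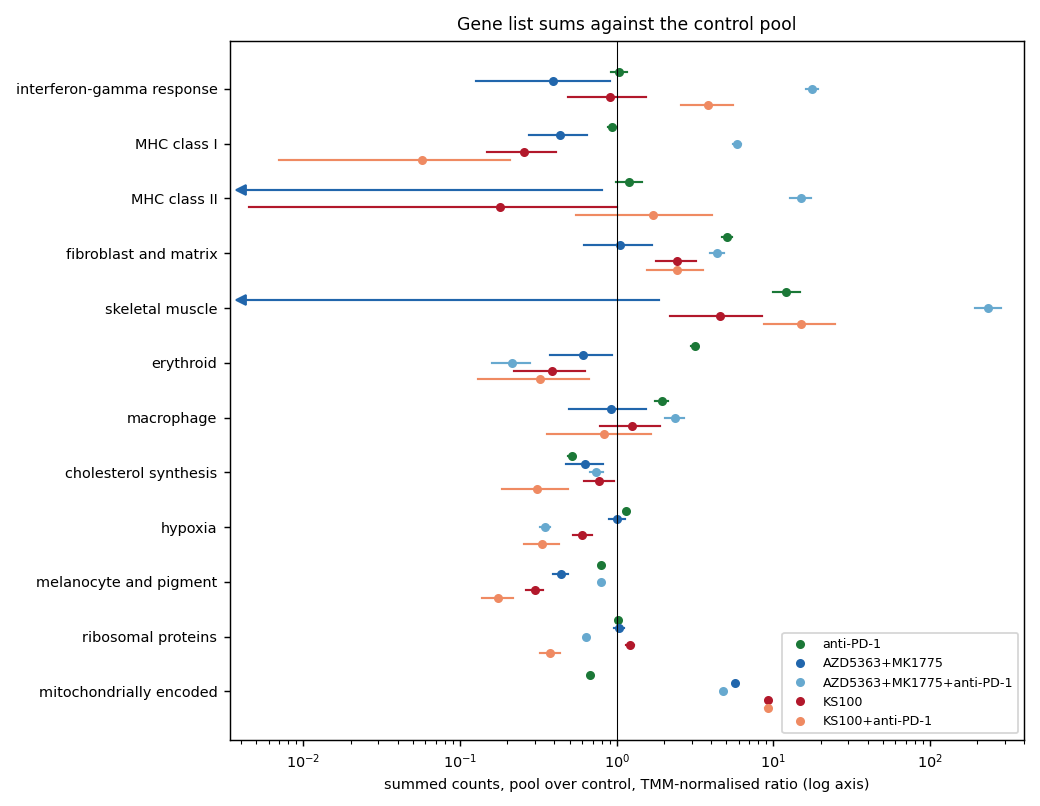
Summed counts of 12 gene lists in each pool over control (TMM-normalised ratio, log axis) with 95% exact intervals from the counts; arrows mark 0 counts. The AZD5363+MK1775+anti-PD-1 pool lies at 17.6 for interferon-gamma response genes and 234 for muscle genes, and the mitochondrially encoded genes lie above 1 in all 4 inhibitor pools.

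The arm effects used all 6 pools in an additive model, in which agreement between the arms stood in for replicates. In the fit of anti-PD-1 across the inhibitor arms the called genes were mostly muscle and mitochondrial genes, and the muscle genes rested on 2 of the 3 arms. Of 7 genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 rose and 2 fell. Myh4 (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446, GRCm38) rose by 5.76 on the log2 scale (SE 1.08, edgeR adjusted p 0.000246). Ttn rose by 4.02 (SE 0.87, edgeR adjusted p 0.00593), Neb, which encodes the thin filament protein nebulin, by 3.78 (SE 0.93, edgeR adjusted p 0.0322) and Car3 by 3.74 (SE 0.89, edgeR adjusted p 0.0242). These 4 were higher with antibody in the pairs with no inhibitor and with AZD5363+MK1775, where Myh4 had 0 counts without and 430 with antibody. The KS100 pair adds little, since Myh4 had 1 count in each pool and the muscle list 11 and 19 counts. Background spread evenly over exons, a rough guide in these pools, would give 12.0 and 14.1. Acta1 was called too, at 0 counts in both KS100 pools. The falls of mt-Co2, by 6.54 on the log2 scale (SE 1.12, edgeR adjusted p 2.5e-05), and of mt-Co3, by 4.52 (SE 1.08, edgeR adjusted p 0.0242), are uncertain for the nuclear copy named above. Rpl28, Rps7, Fth1, Higd1a, Atp6ap2, Cox6c, Cox7b, Hsp90ab1 and mt-Cytb were lower in 3 of 3 pairs without passing the threshold. At an unadjusted p under 0.05 there were 104 genes. With library totals 5 rose and 7 fell, and with DESeq2 size factors 5 and 5. The median log2 change of all genes fitted was 0.08, -0.04 with library totals and 0.36 with no count filter. Left out in turn, the control and anti-PD-1 pools left 13 and 14 genes called, the AZD5363+MK1775 pools without and with antibody 0 and 4, and the KS100 pools, likewise, 12 and 10.

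In the fit of AZD5363+MK1775 across both antibodies, ribosomal RNA and mitochondrial genes were among those that rose and globin genes among those that fell. Of the interferon-gamma and type I interferon lists 1 of 9 and 1 of 3 genes fitted were called higher, and without antibody the interferon-gamma list summed to 0.389 (0.126 to 0.912). Of 66 genes called by edgeR 63 rose and 3 fell. The interferon-induced Parp14 (ENSMUSG00000034422, chromosome 16, 35832874 to 35871544) rose by 5.62 (SE 1.21, edgeR adjusted p 0.00181), Trim12a by 5.24 (SE 1.41, edgeR adjusted p 0.0253), the ceramidase gene Asah2 by 5.63 (SE 1.28, edgeR adjusted p 0.00374) and Malat1 by 4.88 (SE 1.17, edgeR adjusted p 0.00764). mt-Rnr2 rose by 7.37 (SE 2.02, edgeR adjusted p 0.0297) and mt-Rnr1 by 6.68, and mt-Co2 and mt-Atp6 were also called. Iigp1 rose by 4.03 (SE 1.18, edgeR adjusted p 0.0481), with 0 and 300 counts in the 2 AZD5363+MK1775 pools. Slc26a3 and Cr2 had 0 counts in the control and anti-PD-1 pools and at most 5 in either AZD5363+MK1775 pool. Hbb-bt fell by 5.23 (SE 1.28, edgeR adjusted p 0.0089), Hbb-bs by 3.95 (SE 1.16, edgeR adjusted p 0.0499) and Ddit4, a stress-induced inhibitor of mTOR signalling, by 4.27 (SE 1.22, edgeR adjusted p 0.0395). Cyb5a, Cox17, Cox6c, Ndufb9, Rrm2, Polr2c, Srsf7, Mapk1ip1l, Tex30 and Tmem14c were lower in both pairs without passing the threshold. Only 30 of the 63 genes that rose did so in both pairs, 10 of them unnamed gene models, and 23 of the 63 had at most 2 counts in the control and anti-PD-1 pools together. With library totals 22 rose and 4 fell, and the median log2 change of all genes fitted moved from -0.08 to -0.53. It was -0.18 with no count filter. Without the pools in the order above, 18, 9, 203, 13, 17 and 14 genes were called.

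In the fit of KS100 across both antibodies more genes were called higher than lower. Of 378 genes called by edgeR 354 rose and 24 fell. Genes could pass the filter on a few counts in the shallow KS100 pools, where falls were hard to call. The excess of rises is thus not read as an effect of KS100. With at least 50 counts in 2 pools 20 rose and 0 fell, and with all pools thinned 30 and 0. Of the 354 that rose, 273 had counts in both the control and anti-PD-1 pools and 47 were at 0 in both. Among genes silent there, the synaptic adhesion gene Lrfn5 (ENSMUSG00000035653, chromosome 12, 61523150 to 61858342) had 18 counts in the KS100 and 14 in the KS100+anti-PD-1 pool, Treml2 10 and 13, Has2os 27 and 4 and Nxph1 25 and 3, each with 0 in the other 4 pools. Rbm46 had 18 and 6 and Grip1 9 and 11. Ugt1a7c, which shares exons with its neighbours, had 13 and 12, Nrxn3 12 and 8 and Slc26a3 14 and 5, with 0 in the control and anti-PD-1 pools. The fitted changes of such genes depend on the prior count and are not given. Of the 354 genes that rose 348 did so in both pairs, 70 of them unnamed gene models, and 74 had at most 2 counts in the control and anti-PD-1 pools together. Of the 24 genes that fell 12 had 0 counts in both KS100 pools, among them the melanocyte tetraspanin gene Tspan10 against 574 and 332 counts in the control and anti-PD-1 pools, Mcm5, of the replicative helicase, against 480 and 285, Kif15 against 360 and 320, Suclg1 against 403 and 189 and Taldo1 against 351 and 223. Lonrf1, Cpsf6, Atp6ap1 and Glyr1 were at 0 in the KS100 pools too. Of the aldehyde dehydrogenase genes 1 of 3 fitted, Aldh1a3, was called higher (edgeR adjusted p 1.08e-05), on 2 and 4 counts in the control and anti-PD-1 pools and 3 and 7 in the KS100 pools. The pigment gene Pmel fell by 3.02 (SE 0.97, edgeR adjusted p 0.028). The median log2 change of all genes fitted was -0.47, -0.33 with DESeq2 size factors, -0.64 with library totals and 0.01 with no count filter. Without the pools in the order above, 169, 110, 290, 225, 14 and 69 genes were called.

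Between the inhibitors, some antigen-presentation genes were called higher in the AZD5363+MK1775 arm, mostly on counts of its pool with antibody. Without antibody, the MHC class I sums over control had overlapping intervals in the AZD5363+MK1775 and KS100 pools. Of 81 genes called by edgeR for the difference, 7 were higher in that arm and 74 lower. Entry of genes through the shallow KS100 pools bears on this split too. H2-D1 had 3 and 284 counts in the AZD5363+MK1775 pools without and with antibody and 0 in both KS100 pools (edgeR adjusted p 0.00704). The peptide-loading gene Pdia3 had 2 and 164 against 0 and 0 (edgeR adjusted p 0.0268) and Tspan10 5 and 220 (edgeR adjusted p 0.00704). Calr, which serves the same peptide loading, was higher by 4.67 (SE 1.38, edgeR adjusted p 0.045). Irf1, at 0 and 192 counts against 0 and 0, was called too. Lrfn5, Treml2, Grip1, Lama2, Lhx6, Grk4, Ccdc177, Nyap2 and Has2os were lower, each at 0 in both AZD5363+MK1775 pools, and 40 of the 74 lower genes had at most 2 counts in the control and anti-PD-1 pools together. Aldh1a3 was called lower too (edgeR adjusted p 0.0145), at 0 and 1 counts in the AZD5363+MK1775 pools. The median log2 difference of all genes fitted was 0.32, 0.19 with DESeq2 size factors, 0.02 with library totals and -0.22 with no count filter. Without the pools in the order above, 80, 78, 41, 0, 4 and 1 genes were called, and at an unadjusted p under 0.05 there were 433 in the full fit.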

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

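The bound of 1.5-fold for opposite directions, the tests of ribosomal RNA scaling, of muscle tissue, of an even background, of runs of A in expressed transcripts and of the antibody's effect on muscle genes, the splits of the pools and the choice of patterns were made only after the results were seen.

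Erythroid genes went opposite ways with antibody in 2 of the inhibitor arms, which drew attention to them. With no inhibitor the antibody ratio of their summed counts was 3.14 (2.97 to 3.31). In the AZD5363+MK1775 arm it was 0.351 (0.209 to 0.612), with 21 counts in the pool without antibody and 54 in the larger pool with it. The KS100 arm gave 0.839 (0.292 to 2.16), which leaves its direction open. The difference between the arms was not tested. Of the list's 8 members 6 had counts in the control pool, and the list is not specific to red cells. Hbb-bs held 70.9% of the list's counts in the anti-PD-1 pool. Hbb-bs itself had 724 counts in the control pool, 2755 in the anti-PD-1 pool, and 8, 3, 4 and 2 in the inhibitor pools. Its ratio in the AZD5363+MK1775 pair, 0.0512 (0.00876 to 0.214), rests on too few counts for the size rule. No explanation was tested.

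Interferon-response and MHC class I genes were higher in the AZD5363+MK1775+anti-PD-1 pool than in the control pool, with a summed ratio of 8.06 (7.71 to 8.43). Long transcripts were favoured in that pool, yet the median log2 ratio of the 16 genes was 3.33, against -0.26 for lists matched on length and expression, at percentile 100 of 10000 such lists. Scaling in a pool rich in ribosomal RNA is argued against as the whole cause by the lower bound of 4.81 for the summed ratio with library totals. Muscle tissue bringing these genes at one level per muscle count would have given the anti-PD-1 pool a ratio of 1.34, and 0.951 (0.903 to 1) was observed. A response to the inhibitors and antibody together is a candidate explanation, but with 1 pool any difference in tumours, in handling or in labels goes with the treatment and was not tested.

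Of the 354 genes higher in the KS100 arm 47 were at 0 in the control and anti-PD-1 pools and 273 had counts in both, and the first tests below cover silent genes alone. Background spread evenly over exons is argued against, since 46 of 8742 silent genes had 10 or more counts in the 2 KS100 pools, where Poisson draws by exon length gave 0 to 1. Background at sites shared by the inhibitor pools is a candidate explanation: the 74 silent genes at 5 or more counts in the KS100 pool held 4.5 times (3.66 to 5.48) the counts per exon length of other silent genes in the AZD5363+MK1775+anti-PD-1 pool, 6.27 times (5.51 to 7.1) in the KS100+anti-PD-1 pool and 2.8 times (1.37 to 5.13) in the AZD5363+MK1775 pool. An effect of KS100 would also raise the value of the KS100+anti-PD-1 pool. The control and anti-PD-1 pools cannot be used for this question, since the genes were chosen for 0 counts in them. Priming at runs of A is also a candidate explanation, since the 74 genes had a mean longest run of 12.8 bases, against 8.81 in silent genes of similar length (percentile 100). For 220 protein-coding genes of the 273 the mean was 13.3, against 11.8 in genes of similar counts and length (percentile 100), which leaves such priming open for part of them, and an effect of KS100 on either set stays open and untested.

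Skeletal muscle genes were higher in the anti-PD-1 and AZD5363+MK1775+anti-PD-1 pools, with 112 counts of the list in the control pool, 878 and 3444 in those 2, and 0, 11 and 19 in the AZD5363+MK1775, KS100 and KS100+anti-PD-1 pools. Muscle tissue in these pools is a candidate explanation: a second list of 19 muscle genes, none of them in the first, summed to 3.37 (2.47 to 4.64) in the anti-PD-1 pool and 30.3 (22.8 to 40.8) in the combination pool over control. This list held 61, 133 and 243 counts in the control, anti-PD-1 and combination pools, of which Xirp2 had 13, 68 and 53. Its anti-PD-1 ratio thus rested largely on Xirp2. Pygm was at 1, 5 and 34 counts and Ryr1 at 1, 1 and 29. In the first list Acta1 was at 52, 362 and 492 counts and Ttn at 16, 154 and 958 in those pools. Of its 17 members 14 also had counts in the control pool, as had 9 of the second list, and whole tumours were used, with no sort. An effect of the antibody alike in every arm cannot be told apart from this, since the KS100 pair gave 3.31 (1.5 to 7.71) on few counts. They were near the 12.0 and 14.1 of an even background, a rough guide in these pools.

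The anti-PD-1 arm effect called 7 genes. Of the 10 splits of the 6 pools into 3 and 3, 3 gave as many, the real one included, and the highest other split gave 20; 10 splits are too few for a share under 0.05. Inhibitor arm stayed in these fits. Each of the 6 splits that keep an arm together therefore compares the pools of 1 arm by antibody, in either sign: 20 and 20 in the AZD5363+MK1775 arm, 0 and 0 in the KS100 arm and 1 and 1 with no inhibitor. These are no reference without an effect of the antibody. Of the 4 splits with a pool of each arm on either side, the real one gave 7 and the others 4, 0 and 0.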

How the results depend on the processing

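The nuclear protein-coding genes, the genes over 0 in control and anti-PD-1, the thinning and the fits without an inhibitor arm were chosen only after the results were seen. Of 144 alternative values of 14 counts, 72 stayed within 1.5 times the reported count. The cause was not tested, except that stricter minimums, thinning, left-out pools or wider bounds change by construction what can be called.

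Counts for the anti-PD-1, AZD5363+MK1775, KS100 and between-inhibitor effects were 7, 66, 378 and 81. With library totals the first 2 became 12 and 26; with no count filter all but AZD5363+MK1775 became 2, 1270 and 37; with at least 50 counts in 2 pools all became 3, 6, 20 and 2; with limma-voom 19, 248, 663 and 269; and thinned to the shallowest total 2, 5, 30 and 2. The DESeq2 Wald test gave 3 for anti-PD-1. Without the other factor AZD5363+MK1775 gave 295, the inhibitor difference 130 and anti-PD-1 0 by edgeR, with 85 genes at an unadjusted p under 0.05. Without the KS100 pools AZD5363+MK1775 gave 3, without the AZD5363+MK1775 pools anti-PD-1 gave 2, and with genes over 0 in control and anti-PD-1 the difference was 19. DESeq2 size factors and nuclear protein-coding genes kept all 4 counts within 1.5 times. Leaving out each pool gave 0 to 14, 9 to 203, 14 to 290 and 0 to 80; an inhibitor arm left with 1 pool is assumed to vary like the others.

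Pool pairs called 392 genes (anti-PD-1 over control), 233 (AZD5363+MK1775), 506 (KS100), 1848 and 592 (the same 2 with antibody), 413 and 80 (antibody within those 2 arms) and 1579 and 445 (combinations over anti-PD-1). At 3-fold the first fell to 191. With an interval beyond no change, all but AZD5363+MK1775+anti-PD-1 over control moved: 706, 581, 1010, 975, 831, 137, 2511 and 835. With no minimum count the 4 inhibitor pools over control gave 407, 2134, 2829 and 4905, and the last 3 became 227, 2513 and 2567. With at least 50 counts in a pool, KS100 gave 334, its combination 377 over control and 285 over anti-PD-1, and its antibody pair 39. Thinned, all but that pair moved: 10, 55, 70, 79, 125, 80, 84 and 107. DESeq2 size factors and library totals kept all 9 counts within 1.5 times, but with totals 616 genes were higher and 1694 lower in AZD5363+MK1775+anti-PD-1 against control, where TMM gave 1202 and 646. Gene list medians outside the central 95% numbered 108, and 85 to 108 under the alternatives.

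Of 1062 alternative values of 73 arm effects of named genes, 842 kept direction and side of the threshold, 217 lost the threshold, 3 gained it and none changed direction. Of 394 values of 197 named pool ratios under the other scalings, 342 stayed within their interval, 52 moved beyond, and 1, Rplp1 (not past the rule), crossed 1. Of 200 alternative list sums, 139 stayed within their intervals and 60 moved beyond; with DESeq2 size factors and with library totals, 7 intervals each changed between holding and leaving out 1. Among sums whose interval left out 1, 1 changed direction: heat shock genes in the AZD5363+MK1775+anti-PD-1 pool over control, at 1.24 (1.19 to 1.3) with TMM and 0.776 (0.742 to 0.811) with library totals, so their direction rests on the scaling. Where the interval held 1, 3 values of 2 sums crossed it: heat shock genes in the KS100 pool and mitochondrially encoded genes in KS100+anti-PD-1 over KS100.

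No paired analysis was possible because the labels give no replicate numbers shared across groups and each treatment has 1 pool; the antibody effect took the inhibitor arm as a factor instead. Depth limits the inhibitor pools most: 3 counts were 112.6 CPM in the AZD5363+MK1775 pool and 1.89 CPM in the control pool.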

Other observations

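The gene lists and genes below were chosen only after the results were seen, and no explanation of them was tested.

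Mitosis, glycolysis, NRF2, heat shock and immediate early genes went both ways within a list in the AZD5363+MK1775+anti-PD-1 pool against control. Of 23 mitosis genes tested 2 were higher, Cenpe at 6.97-fold (4.93 to 9.85) and Cenpf at 2.82-fold (2.12 to 3.71), and 2 lower, Cdk1 at 0.208 and Birc5 at 0.387 (0.312 to 0.475), with a summed ratio of 0.922 (0.866 to 0.981). Of 13 glycolysis genes 4 were higher, Aldoa at 5.78-fold (5.10 to 6.55), Hk2 at 4.22-fold, Slc16a3 at 3.06-fold (2.03 to 4.52) and Eno1, which has processed pseudogenes, at 2.41-fold, and Ldha was lower at 0.232, with a sum of 0.754 (0.714 to 0.795). Of 13 NRF2 targets, which summed to 0.524 (0.479 to 0.571), Gclc was higher at 4.40-fold (2.48 to 7.63), and Hmox1 at 0.095 (0.0114 to 0.349), Gsta4 at 0.14 (0.0451 to 0.331) and Fth1 at 0.271 were lower. Of 10 heat shock genes 3 were higher, Hsp90aa1 at 2.58-fold (2.33 to 2.84), Hsph1 at 2.35-fold and Hspa4l at 2.81-fold, and 3 lower, Dnajb1 at 0.121, Bag3 at 0.362 and Hspa1b. Of 10 immediate early genes Klf6 was higher at 3.83-fold (2.79 to 5.21), and Nr4a1 at 0.0987 (0.036 to 0.216) and Ier3 at 0.235 (0.106 to 0.452) were lower. These ratios are relative to TMM scaling, and with library totals the median log2 ratio of all genes tested was -0.65. They were also not matched on exon length, with which ratios rose in this pool.

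Beyond the genes described above, the anti-PD-1 pool differed from control in some hypoxia, glycolysis, dedifferentiation and aldehyde dehydrogenase genes. Hypoxia genes went both ways, with 3 of 20 higher and 3 lower, as did glycolysis genes, with 1 of 13 higher and 3 lower. The hypoxia-induced Angptl4 was higher at 21.6-fold (6.91 to 109), Ndrg1 at 2.5-fold (1.94 to 3.22) and the lactate exporter gene Slc16a3 at 2.30-fold (1.75 to 3.03), while Hk2 was lower at 0.469 (0.373 to 0.585). Of 8 dedifferentiation genes 3 were higher, Tnc at 6.65-fold (3.59 to 13.3) among them, with a sum of 1.54 (1.30 to 1.83). Of 9 aldehyde dehydrogenase genes 1 was higher, with a sum of 1.28 (1.15 to 1.42). No mitosis gene of 23 and no type I interferon gene of 4 was past the rule, with sums of 0.831 (0.803 to 0.86) and 0.852 (0.745 to 0.975).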
